A study of Mus musculus with 4 samples.

How the data were processed

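The deposited counts are UMI counts per gene and barcode from 10x libraries, made with Cell Ranger against mm10 per the submitters' processing notes, which list versions 3.1.0 and 3.10. The 4 libraries hold 31053 genes and 20765 barcodes, and the lowest barcode total is 500 UMIs, so barcodes below it had been removed before deposit. Whether the libraries were brought to equal depth when they were joined is not given in the sources used here, and neither is the number of animals per library. Gene positions came from GENCODE M21, and 292 of 294 named genes carried the same gene ID there. The groups and comparisons, the rule of size, the gene lists and most alternatives were fixed before the data were examined.

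Cells were kept with at least 200 genes, at least 500 UMIs and at most 15% mitochondrial UMIs. The gene minimum dropped 452 (IT-TT), 517 (IT), 791 (TT) and 884 (none) barcodes and the mitochondrial limit a further 474, 1651, 1565 and 418. Barcodes that were dropped held 33.5%, 11.3%, 2.28% and 48.8% haemoglobin UMIs. Scrublet as called in scanpy marked under 0.5% of cells by its automatic threshold, so the highest scores were removed up to 0.8% per 1000 cells, which took 89, 321, 61 and 19 cells. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen with library as batch, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 19 clusters without integration of libraries. T and NK cells were clustered again on 1000 variable genes. The random seed was 1.

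A class was considered for a cluster if its mean marker score reached 0.2 and at least 3 of its markers were detected in at least 10% of the cells. The cluster took the class with the most markers among its top 10 genes, and the mean score broke ties. A marker counted only if it reached 50 CPM in its highest cluster, and scores were scaled to that highest level. These naming constants, the joint class of melanoma and Schwann cell markers called Sox10-positive, and a rule that leaves a cluster unnamed if its top genes hold 3 epithelial genes were set after the clusters were seen. The epithelial rule kept 2.98% (IT-TT), 0.050% (IT), 0.074% (TT) and 0.195% (none) of cells out of the plasma cell class. Clusters 16 and 18 reached the score (0.219 for Sox10-positive, 0.202 for macrophage and monocyte) but stayed unnamed by a further rule, a median UMI count far below that of their library (0.224 and 0.166 of it) and no marker among the top 10 genes. Clusters 6 and 17, with similar scores of 0.219 and 0.205 and no marker among the top 10 genes either, had more UMIs and were named Sox10-positive. The low-UMI cells held 0.154%, 27.5%, 0.074% and 3.90%. Some markers that named the classes, such as Dct, Tyrp1, Chil3 and Gzma, are also reported. With the reported markers left out of clusters and names, the Sox10-positive class kept 1468 of 1468 (IT-TT), 3568 of 3625 (IT), 2246 of 2246 (TT) and 1281 of 1284 (none) of its cells.

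Shares carry exact Clopper-Pearson intervals and differences of shares Newcombe intervals, both at 95% and for counting error only. Counts of each class were summed per library and scaled to CPM, the count times 1e6 over the class sum. A gene passed the rule of size if its ratio was at least 2, the exact conditional binomial 95% interval of the ratio excluded 1, its CPM was at least 20 in the higher library and it had at least 20 UMIs over both sums. A class needed 50 cells in both libraries, which T and NK cells reached only in IT-TT and IT. With 1 library per group no test between groups was made. Where a library had 0 counts the fold is a lower bound at a floor of 3 counts. Such a bound shrinks with the class sum, so it falls on thinning even at unchanged expression. The genes named were the 5 higher and 5 lower with the largest bound nearest 1 in the main comparison and 3 and 3 in the others, 12 genes named in every comparison, and up to 4 members of each list with the highest summed UMIs.

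There were 32 gene lists. A member needed 5 UMIs and a list 3 such members, and the list of X and Y chromosome genes had fewer and gave no value. Each list median was ranked among 10000 random lists matched over 20 expression bins. Genes with 0 counts in 1 library took the log2 ratio at the floor of 3 counts, or 0 where the floor would turn its sign. A gene with 0 counts in both libraries took 0 too. A gene's log2 ratio given as 0.0 is thus a set value and not a measured ratio of 1. The limit at 0 was added after list values were seen, because the floor alone gave some of these genes the wrong sign. Genes under 0.5 of their highest CPM over the classes may hold RNA from other cells. They were left out of the genes named for the largest folds and, in 1 alternative, of the gene counts. Also not named for their fold were mitochondrial, ribosomal protein and haemoglobin genes, receptor and immunoglobulin variable segments, and genes named only by number. List members were named without these filters.

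Other settings chosen from the start were a minimum of 500 genes, mitochondrial limits of 10% and 25%, doublets kept, Leiden resolutions of 0.5 and 2, classes by marker score per cell, each library clustered alone, TMM scaling, no CPM minimum or one of 100, cells thinned to 1000 UMIs, the mean over cells, genes with RNA from other cells left out, means in place of medians, and gated T cell subsets. Chosen after seeing the data were no mitochondrial limit, a minimum of 1000 UMIs, a total without erythroid and unnamed cells, mitochondrial limits of 10% and none for genes, and class markers left out of clusters and names.

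The rule of size was tested on simulated data made from these libraries with 50 genes at each true fold. Both libraries were drawn as Poisson counts from the pooled profile of the compared libraries. The simulation thus holds counting error only, and gives no rate of false calls under variation between tumours or cells. In Sox10-positive cells, IT-TT against IT, it called 50 of 50 genes changed 3-fold, 29 of 50 changed 2-fold, 0 of 50 changed 1.5-fold and 0 of 5577 unchanged genes. In macrophages and monocytes of TT and none it called 47 of 50 genes changed 3-fold and 43 of 5163 unchanged genes. In T and NK cells it called 47 of 50 genes changed 4-fold, 36 of 50 changed 3-fold and 78 of 5080 unchanged genes (1.54%). A list shifted by 1.0 on the log2 scale came back as 0.995 in Sox10-positive cells and 0.771 in T and NK cells.

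The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, umap-learn 0.5.12, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors. Raw reads were not analysed here. Results for some withheld items are not reported here.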

Results

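Single-cell RNA sequencing was run on cell suspensions of subcutaneous SW1 tumours, a mouse melanoma model grown in Matrigel, from 4 treatment groups. The group IT-TT received 2 doses of anti-PD1, an antibody that blocks an inhibitory receptor of T cells, followed from day 10 by a drug combination. The combination was ceritinib at 25 mg/kg, an inhibitor of ALK and related tyrosine kinases, and trametinib at 1 mg/kg, an inhibitor of the MAPK pathway kinase MEK. The group IT received anti-PD1 and vehicle, the group TT control IgG and the combination, and the group called none control IgG and vehicle. Each group was 1 library, so no difference between groups has a replicate check. The libraries held 24903900 (IT-TT), 47380404 (IT), 31487733 (TT) and 16948692 (none) UMIs over 4269, 8507, 5128 and 2861 barcodes. After filtering, 3254, 6018, 2711 and 1540 cells remained, with a median of 5394, 4508, 7531 and 8041 UMIs per cell. Fixed markers named cells as Sox10-positive (melanoma and Schwann cell markers could not be separated and were taken as 1 class), macrophage and monocyte, T and NK, neutrophil, fibroblast, endothelial and erythroid. Ranges in brackets are exact 95% intervals, or Newcombe intervals for differences of shares, and they cover counting error only.

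The series design contrasts anti-PD1 alone with anti-PD1 followed by the combination, which asks what the combination adds to a tumour already treated with the antibody. T and NK cells, a class that includes lymphocytes that kill tumour cells as well as CD4 and regulatory T cells, made up 14.8% (13.5 to 16.0) of the kept cells of IT-TT and 1.38% (1.10 to 1.71) of those of IT, a difference of 13.4 percentage points (12.2 to 14.7). Macrophages and monocytes, the main phagocytes of tumours, took 15.5% (14.2 to 16.7) in IT-TT and 3.41% (2.96 to 3.90) in IT. Neutrophils took 5.44% against 0.316%, fibroblasts, which build the tumour stroma, 12.4% against 0.615%, and endothelial cells, which line vessels, 3.07% against 0.033%. Among immune cells alone, T and NK cells held 41.4% in IT-TT and 27.0% in IT, 14.3 points apart (8.41 to 19.8). Among host cells, here the named cells other than Sox10-positive and erythroid cells, they held 28.8% and 24.0%, 4.86 points apart (−0.364 to 9.61). Erythroid cells left out of this total numbered 20 in IT-TT and 391 in IT, beside 1664 and 346 host cells. Counting them would lower the T and NK share of IT by more than that of IT-TT. For macrophages and monocytes the direction turned with the total: they held 43.4% against 66.8% of immune cells (−23.4 points, −29.2 to −17.3) and 30.2% against 59.2% of host cells (−29.0 points, −34.5 to −23.3). Sox10-positive cells held 45.1% in IT-TT and 60.2% in IT, a difference of −15.1 points that became 6.01 points with a mitochondrial limit of 10% and 8.53 points with none. Unnamed cells held 3.14% of IT-TT and 27.5% of IT, and most of those of IT were in cluster 16, which scored highest for Sox10-positive markers but stayed unnamed for its low UMI count and the lack of a marker among its top 10 genes. The mitochondrial limit of 15% dropped 11.1% of the barcodes of IT-TT, 19.4% of IT, 30.5% of TT and 14.6% of none.

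**Figure D1:**
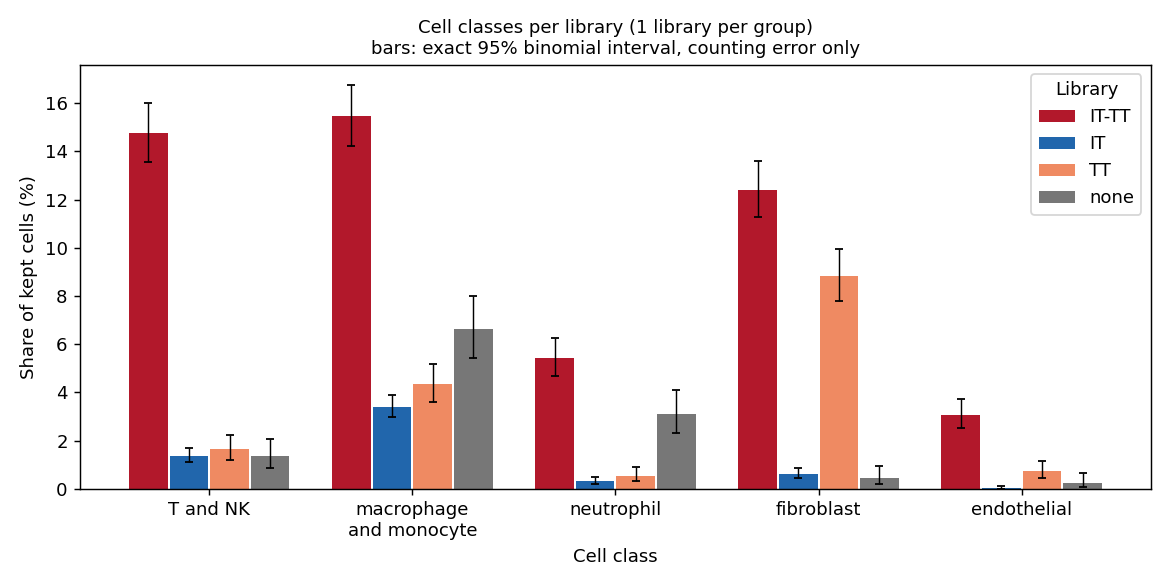
Share of kept cells (percent, vertical axis) held by T and NK, macrophage and monocyte, neutrophil, fibroblast and endothelial cells in each of the 4 libraries. Error bars are exact 95% binomial intervals for counting error only. Sox10-positive, erythroid and unnamed cells are not shown. T and NK cells stand at 14.8% in IT-TT and between 1.36% and 1.66% in the other 3 libraries.

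In Sox10-positive cells, genes of melanocyte differentiation stood far higher in IT-TT than in IT, and genes driven by the MAPK pathway, cell division and glycolysis stood lower. Dct, which encodes a pigment synthesis enzyme, was 104-fold higher (88.8 to 122; 511 against 4.94 CPM), and Tyrp1, another pigment enzyme, was 72.5-fold higher (64.9 to 81.1). Pmel, a melanosome protein gene, was 48.3-fold higher (38 to 62.2), Mal, a myelin protein gene, 181-fold (69.4 to 670), and Mlana had 222 UMIs against 1, a ratio of 858 (152 to 34041). Cytl1, a cytokine-like gene, was 515-fold lower (237 to 1404) and Etv4, an ETS factor gene induced by MAPK signalling, 41.4-fold (24.2 to 77.9). Arc was 31-fold lower (18.8 to 55.6), Hmga2, a chromatin protein gene, 24.8-fold (19.6 to 31.9) and Ube2c, a mitotic ubiquitin enzyme gene, 23.9-fold (17.4 to 33.9). In all, 802 genes were at least 2-fold apart by the rule of size, 535 higher and 267 lower in IT-TT.

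Of 21 measured members of the MAPK output list, 13 fell and 0 rose, and their median log2 ratio of −1.32 was at percentile 0.0 of 10000 random matched lists, given here as a description of these libraries. Egr1, an immediate early factor gene, fell 3.38-fold (3.26 to 3.52), Ccnd1, the cyclin D1 gene, 3.63-fold (3.46 to 3.82), and the MAPK feedback genes Dusp6 and Spry4 fell 2.27-fold (2.1 to 2.46) and 5.01-fold (3.76 to 6.81). In the proliferation list 14 of 26 members fell and 0 rose, among them Cenpf (6.48-fold), Top2a (9.83-fold) and Mki67 (7.7-fold). Hypoxia and glycolysis genes fell in 20 of 22 cases, with Gapdh 4.77-fold (4.68 to 4.85), Pkm 4.42-fold, Mif 3.85-fold and Tpi1 3.71-fold lower. Melanocyte differentiation genes rose in 5 of 13 cases, with a median log2 ratio of 2.87 at percentile 100.0. MHC class I and antigen processing genes, which present peptides to CD8 T cells, rose in 10 of 21 cases, including B2m (2.16-fold, 2.09 to 2.23), H2-D1 (3.48-fold, 3.33 to 3.63) and the immunoproteasome genes Psmb10 (2.48-fold) and Psmb8 (4.6-fold, 4.16 to 5.09). The list member H2-K1 stayed near absent, at 17.5 CPM in IT-TT and 3.84 CPM over the vehicle libraries. Its mean over host classes of the combination libraries was 2196 CPM. In the interferon gamma response list 7 of 26 members rose. Gbp7 was 11.3-fold (9.63 to 13.3), Irf1 5.27-fold (4.48 to 6.2) and Igtp 11.2-fold (9.03 to 13.9) higher. MHC class II genes rose in 4 of 9 cases, but at low levels. Cd74 reached 113 CPM against 15225 CPM in macrophages and monocytes. In this library 24 host genes at low levels in vehicle Sox10-positive cells (at most 6.77 CPM, Btg2) stood at 0.0072 of their host level, close to that ratio. FoxO and growth factor withdrawal genes rose in 3 of 18 cases (Txnip 4.31-fold, Bcl2l11 2.35-fold, Cdkn1b 2.3-fold) and fell in 1 case, Igf1r, a growth factor receptor gene (3.18-fold). Bmp7, a bone morphogenetic protein gene, fell 3.27-fold (2.64 to 4.08), while Cd274, which encodes the PD1 ligand PD-L1, had 9 and 10 UMIs, too few to compare.

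Dct, Tyrp1, Pmel and Mlana were also markers that named the class, and with the reported markers left out of clusters and names their log2 ratios were 6.66, 6.13, 5.56 and 9.71, against 6.69, 6.18, 5.59 and 9.74 with them. TMM scaling shifted all log2 ratios of this comparison by −0.33, which left 224 genes higher and 459 lower and put B2m, Psmb10, Cd74, Bcl2l11 and Cdkn1b below 2-fold. Without a CPM minimum 2131 genes passed, and with a minimum of 100 CPM 242. Clusters 3, 4 and 10 held most Sox10-positive cells of IT-TT and clusters 6, 9, 13 and 17 most of those of IT, with median depths of 5347 and 8632 UMIs, and haemoglobin genes, which mark RNA from red cells, were lower in IT-TT in 3 of 4 cases.

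Macrophages and monocytes of IT-TT had higher interferon gamma response and antigen presentation genes than those of IT, and lower cell cycle genes. Once genes whose RNA may come from other cells were left out, those with the largest rises were Hopx (22.4-fold, 12.1 to 46.8), F10, the coagulation factor X gene (18.9-fold, 11.9 to 32), Chil3, a chitinase-like gene of inflammatory monocytes (21.5-fold, 11.3 to 47.1), Gpr141 (16.4-fold, 7.9 to 41) and Spink2 (333 against 2 UMIs, 38.8-fold, 10.6 to 321). Those with the largest falls were Camk2n1 (69.8-fold, 26 to 264), Fcrls (16.3-fold, 13.9 to 19.4), the scavenger receptor gene Cd163 (10.9-fold, 8.03 to 15), Zmynd15 (10.5-fold, 8.31 to 13.3) and Cd81 (8.84-fold, 7.85 to 9.98). The rule of size passed 933 genes, 430 higher and 503 lower. Of 26 interferon gamma response genes 17 rose and 1 fell, with a median log2 ratio of 2.11 at percentile 100.0. Irf1 rose 8.29-fold (5.54 to 13), Ciita, the master regulator gene of MHC class II, 4.22-fold (3 to 6.12) and Zbp1 2.59-fold (2.01 to 3.38). Antigen presentation genes rose too, 9 of 21 of MHC class I (B2m 2.08-fold, Psmb9 2.71-fold) and 4 of 11 of MHC class II (H2-Aa 2.26-fold, H2-DMa 2.65-fold), with 0 lower. Dendritic cell maturation genes rose in 5 of 18 cases and fell in 1. Immature myeloid and suppressive genes rose in 8 of 19 cases and fell in 1, including Cebpb (4.88-fold), the monocyte gene Ly6c2 (10.7-fold, 7.85 to 15.1) and S100a8, a neutrophil and monocyte gene (1155 against 2 UMIs). S100a8 was also a top gene of the neutrophil cluster, with 177 cells in IT-TT and 19 in IT. The source of its UMIs in the macrophage and monocyte class was not tested. Among alternatively activated macrophage genes 4 of 21 rose and 6 fell. Mrc1, a mannose receptor gene, fell 3.13-fold (2.76 to 3.55) and Ccl8, a chemokine gene, 3.22-fold. Arg1, the arginase gene, was 1.1-fold lower (0.941 to 1.28) and did not pass. Cxcl9, a chemokine gene that draws T cells, rose 2.42-fold (1.82 to 3.28), Cxcl10 fell 3.37-fold, and Nos2 had 26 against 0 UMIs, too little to pass. Proliferation genes fell in 18 of 26 cases (Mki67 4.6-fold), MAPK output genes in 7 of 21 with 1 risen, and hypoxia and glycolysis genes in 12 of 22. Cd274 was 2.96-fold higher (1.72 to 5.52), but −0.52 on the log2 scale once cells were thinned to 1000 UMIs. Thinning left 1000 UMIs in each of 189 cells of IT, from a class sum of 1233615. The thinned value thus rests on few Cd274 UMIs and has no interval.

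Cluster 7 held 449 of the 503 myeloid cells of IT-TT and cluster 15 held 172 of the 205 of IT, with median depths of 10553 and 3438 UMIs, and the haemoglobin list fell with a median log2 ratio of −4.68. The median was −0.864 for mitochondrially encoded genes and −0.268 for dissociation and heat shock stress genes. Thinning left 622 genes, 400 higher and 222 lower, and put Mrc1 and Psmb8 below 2-fold. In all, 505 genes passed once those with RNA from other cells were left out, 242 with a minimum of 100 CPM and 1624 with none.

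T and NK cells of IT-TT differed from those of IT in single effector and exhaustion genes and in subset make-up. Genes were summed over all subsets, so their differences cannot be told apart here from that make-up. Gzmk, Rgs16, Lag3 and Pdcd1 were among the top genes of a CD8 subcluster, and Gzma of an NK subcluster. Gzmc, a granzyme gene, had 687 UMIs against 0 and was at least 20.1-fold higher. Il17a, a cytokine gene, was at least 6.95-fold (238 against 0), Cd40lg, a T cell help gene, at least 4.85-fold (166 against 0), Tmem176a 10.7-fold (4.14 to 39.3) and Emb 6.51-fold (3.86 to 11.9) higher. Tox, a transcription factor gene of exhausted T cells, was 4.9-fold lower (3.54 to 6.72), Gzmk 4.44-fold (3.22 to 6.06), Rgs16 4.65-fold (3.22 to 6.6), Prdm1 5.55-fold (2.98 to 10) and Dapl1 13.5-fold (5.58 to 33.3) lower. Pdcd1, which encodes PD1, fell 2.55-fold (1.99 to 3.22), from 539 to 212 CPM. By the rule of size 565 genes passed, 275 higher and 290 lower.

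Cytotoxic effector genes rose in 7 of 17 cases and fell in 2, but their median log2 ratio was −0.16 at percentile 14.5, so the list as a whole was not higher. Gzma rose 3.96-fold (3.03 to 5.29), Gzmb 3.29-fold (1.77 to 6.91), Srgn 2.08-fold and Ctsw 2.08-fold, and the chemokine gene Ccl5 fell 3-fold (2.86 to 3.14). T cell activation and exhaustion genes rose in 6 of 22 cases, among them the costimulatory receptor gene Icos (3.79-fold, 2.2 to 7.17) and Cd69 (2.09-fold), and fell in 7, with a median log2 ratio of −0.26 at percentile 4.95, inside the middle 95% of random lists. T helper 1 genes rose in 7 of 13 cases and fell in 1, with Hopx 4.76-fold and Il18r1 3.95-fold higher, while Ifng itself was 1.3-fold lower (0.963 to 1.72) and did not pass. Naive or memory genes rose in 3 of 17 cases and fell in 4. Il7r, a survival receptor gene, rose 5.48-fold (3.53 to 9), Tcf7 2.22-fold and S1pr1 5.04-fold (1.36 to 42.1, 115 against 2 UMIs), and Ccr7 fell 2.47-fold. Regulatory T cell genes rose in 2 of 14 cases and fell in 2, and Foxp3 was 1.37-fold higher (0.442 to 6.89) on 47 against 3 UMIs. Hypoxia and glycolysis genes fell in 7 of 20 cases, such as Pgk1 (2.49-fold), and the MAPK feedback gene Dusp6 fell 7.61-fold (2.7 to 20.2). CD8 T cells held 29.0% of the T and NK cells of IT-TT and 72.3% of those of IT, a difference of −43.3 points (−52.7 to −32.1) that was −26.5 points (−37.4 to −15.0) when CD8 cells were gated on a UMI of Cd8a or Cd8b1. Conventional CD4 T cells held 28.8% against 12.0% (16.7 points, 7.16 to 23.5), NK cells 30.6% against 8.43% (22.2 points, 13.3 to 28.2) and regulatory T cells 11.7% against 7.23% (4.44 points, −3.64 to 9.45). The conventional CD4 difference was 8.62 points with at least 500 genes per cell, and the regulatory T difference −0.507 points with doublets kept. Gating on a Cd4 UMI gave 60 conventional CD4 T cells of 480 in IT-TT and 0 of 83 in IT. Subclusters had named 138 and 10, so fewer cells had a Cd4 UMI than were named so. Regulatory T cells gated on a Foxp3 UMI held 5.63% and 3.61%. No subcluster was named gamma-delta T, and the share of such cells was not measured here. After thinning to 1000 UMIs, 12.4% of 460 cells in IT-TT and 31.5% of 54 in IT had a Cd8a UMI (25.0% and 47.0% unthinned, 20 and 29 cells left out). Beside this stood 0 of 1459 Sox10-positive cells of IT-TT (exact interval up to 0.253%) and 0.028% of 3587 of IT. Median depths in IT-TT and IT were 3503 and 2181.5 UMIs in T and NK cells and 5365 and 8693 in Sox10-positive cells.

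The 83 T and NK cells of IT had a median of 1416 UMIs against 3384 in IT-TT, and all 3 measured haemoglobin genes were lower in IT-TT (Hbb-bs 23.6-fold). In the subcluster that held most CD8 cells of IT, 55 of 57 cells came from IT, and Mgp and haemoglobin genes led it as well, so this subcluster may be that library and not a type. TMM scaling shifted log2 ratios by 0.16 and left 394 genes higher and 202 lower, and thinning left 239 genes and put Il17a, Cd40lg, Tcf7, S1pr1 and Ccr7 below 2-fold. At 0 UMIs in IT, Il17a and Cd40lg have lower bounds that must shrink as thinning lowers the class sum.

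The contrast of TT with none asks what the combination did without the antibody. In Sox10-positive cells melanocyte genes were again higher, with Dct 224-fold (170 to 303; 870 against 3.88 CPM), Pmel 227-fold (126 to 454) and Tyrp1 73.1-fold (59.3 to 91.3), and Pcolce2, a collagen processing gene, had 1715 UMIs against 1 (1167-fold, 209 to 46115). Cytl1 was 923-fold lower (516 to 1850), and the granzyme genes Gzme (0 against 754 UMIs, at least 369-fold) and Gzmd (2 against 673 UMIs, 495-fold, 136 to 4092) were lower too. MAPK output genes fell in 9 of 21 cases with 0 risen, among them Ccnd1 (4.08-fold, 3.93 to 4.22), Hmga2 (33.1-fold, 27.5 to 40.1), Etv5 (5.09-fold) and Spry4 (5.56-fold, 4.56 to 6.83). Dusp6 stood at a ratio of 1.01 (0.958 to 1.06). Proliferation genes fell in 12 of 26 cases and rose in 1 (Cenpf 8.12-fold, Mki67 6.93-fold lower), and hypoxia and glycolysis genes fell in 18 of 22 (Gapdh 2.93-fold, Pkm 3.65-fold). MHC class I genes rose in 2 of 21 cases, Psmb8 (20.7-fold, 12.2 to 38.2) and Psmb10 (2.42-fold), with a median log2 ratio of 0.973 at percentile 100.0. Of 22 interferon gamma response genes 2 rose, among them Gbp9 (13.6-fold), and 2 fell (Irf8 39.5-fold, Cxcl10 2.04-fold). The median log2 ratio of this list was 1.20 at percentile 100.0. Type I interferon genes had 0 members past the rule and a median log2 ratio of −1.90 at percentile 0.0. Bmp7 was 1.38-fold higher (1.22 to 1.57) and did not pass. The rule of size passed 826 genes, 454 higher and 372 lower, and 6 of 13 mitochondrially encoded genes rose, with kept cells at a median of 9.92% mitochondrial UMIs in TT and 5.23% in none.

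In macrophages and monocytes the same contrast had lower genes of the type I interferon response, the antiviral program, of which 22 of 27 members fell and 0 rose (median log2 ratio −2.36, percentile 0.0). Rsad2, an antiviral enzyme gene, fell 427-fold (166 to 1571), Isg15 19.8-fold (14.3 to 28.1), Irf7 5.87-fold (4.33 to 8.06) and Bst2 2.64-fold (2.04 to 3.42). Ifit1bl1 and Cd209d, at 0 UMIs in TT, were at least 81.4-fold and at least 65.9-fold lower, and Ccl5 at least 57-fold lower. Interferon gamma response genes fell in 5 of 22 cases and rose in 1, with Cxcl10 36.5-fold (24 to 58.3) and Cd274 3.85-fold lower. Alternatively activated macrophage genes fell in 8 of 20 cases and rose in 2, with Arg1 4.29-fold lower (3.7 to 4.98). Chil3 (11.1-fold, 5.75 to 24.6), Nr4a2 (11.1-fold, 6.08 to 22.4) and Igkc, an immunoglobulin gene (133 against 1 UMIs, 59.9-fold, 10.6 to 2383), were higher. In total 667 genes passed, 309 higher and 358 lower. The T and NK share was 1.66% (1.21 to 2.22) in TT and 1.36% (0.846 to 2.08) in none, 0.296 points apart (−0.529 to 1.02), but 25.3% and 12.3% of immune cells (a difference of 4.81 to 21.0 points) and 10.3% and 11.5% of host cells (−1.24 points, −7.25 to 3.78). Macrophages and monocytes held 4.35% and 6.62% (−2.27 points, −3.80 to −0.860), or 66.3% and 59.6% of immune cells (6.64 points, −3.46 to 16.6) and 27.0% and 56.0% of host cells (−29.0 points, −37.1 to −20.6). Fibroblasts held 8.82% and 0.455% of kept cells (8.36 points, 7.24 to 9.51).

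For TT against none the myeloid difference became 0.272 points with a mitochondrial limit of 10%. The log2 ratio of Igkc was then set to 0.0, because a count of 0 left no ratio. With each library clustered alone, the T and NK difference was 1.66 points of kept cells and 25.1 points of immune cells, and the myeloid difference was −4.70 points of immune cells. Thinning left 154 myeloid genes, a log2 ratio of 0.0 for Cd274 and −0.88 for Arg1. In Sox10-positive cells TMM scaling shifted ratios by −0.12 and left 342 genes higher and 459 lower, and clusters 3, 4 and 10 held most cells of TT and 6, 9, 13 and 17 most of none. With a minimum of 100 CPM 269 genes passed, with none 2134. Cluster 7 held 86 of the 118 myeloid cells of TT and cluster 15 held 73 of the 102 of none, at median depths of 10796.5 and 5149 UMIs, and all 4 haemoglobin genes were higher in TT (median log2 ratio 2.51). That direction did not hold: all 4 were lower in TT with a mitochondrial limit of 10% (Hbb-bs −3.23 on the log2 scale), and the list median was −3.13 with classes by marker score per cell.

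The contrast of IT with none asks what the antibody did without the combination. In Sox10-positive cells 28 genes passed the rule, 9 higher and 19 lower, none of them in the MAPK, proliferation, melanocyte or hypoxia lists. Bcas1 (2.34-fold, 1.97 to 2.8), Gstp1 (2.08-fold, 1.76 to 2.48) and Cldn19 (2.02-fold, 1.7 to 2.43) were higher, and Gzmd (101-fold, 63.2 to 171), Gzme (30.3-fold, 23.6 to 39.5) and Creb5 (8.18-fold, 7.2 to 9.32) lower. MHC class I genes rose in 2 of 21 cases, Psmb8 (18.7-fold, 11.1 to 34.4) and H2-D1 (2.03-fold, 1.88 to 2.19), with a list median of 0.41 at percentile 100.0, and the chemokine genes Cxcl2 (41.8-fold) and Cxcl1 (17.4-fold), which draw neutrophils, fell. Cd74 rose 10-fold (7.69 to 13.2), from 4.59 to 45.9 CPM, with 7703 CPM in the macrophages and monocytes of IT. In macrophages and monocytes 563 genes passed, 221 higher and 342 lower, and type I interferon genes fell in 18 of 27 cases with 0 risen (Rsad2 15.5-fold, Isg15 5.46-fold, Irf7 4.73-fold, Slfn5 6.55-fold). Of 22 genes of the interferon gamma response 7 fell (Cxcl10 3.63-fold, 3.06 to 4.33) and 1 rose, Cxcl9 (52 against 1 UMIs, 26.4-fold, 4.53 to 1063). Immature myeloid genes fell in 6 of 16, such as Arg1 (4.89-fold, 4.16 to 5.76). MHC class II genes rose in 3 of 11 cases (H2-Eb1 2.1-fold, H2-Ab1 2-fold), and Mucl1 (at least 13.2-fold), Retnla (136 against 2 UMIs, 34.5-fold) and Igkc (106 against 1 UMIs, 53.8-fold) were higher. Ifit1bl1 (at least 72.2-fold), Mmp13 (at least 27.6-fold) and Cmpk2 (35-fold, 13.1 to 132) were lower. Cd274 was 3.66-fold lower (1.84 to 7.58) and 0.52 on the log2 scale after thinning, a value on few UMIs and without an interval. The T and NK share was 1.38% in IT and 1.36% in none, 0.016 points apart (−0.744 to 0.588), but 27.0% and 12.3% of immune cells (14.8 points, 7.34 to 21.4) and 24.0% and 11.5% of host cells (12.5 points, 5.57 to 18.6). Macrophages and monocytes held 3.41% and 6.62% (−3.22 points, −4.64 to −1.98), or 66.8% and 59.6% of immune cells (7.13 points, −1.79 to 16.1) and 59.2% and 56.0% of host cells (3.21 points, −5.56 to 12.0).

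For IT against none, 10 Sox10-positive genes passed once those with RNA from other cells were left out, 5 with a minimum of 100 CPM and 367 with none. Thinning left 59 Sox10-positive and 163 myeloid genes, put Bcas1, Cldn19, H2-Eb1, H2-Ab1, Mucl1 and Cxcl9 below 2-fold, and moved the count of lists outside the middle 95% of random lists in myeloid cells from 13 to 8. The fold of Mucl1 is a lower bound, which must shrink as thinning lowers the class sum. The T and NK difference became 1.41 points when each library was clustered alone and 0.658 without erythroid and unnamed cells, and the myeloid difference became −4.95 and −1.80 points. Of immune cells, clustering each library alone gave 30.7 points (25.1 to 36.4) for T and NK cells and −8.00 points (−16.6 to 1.05) for myeloid cells. In myeloid cells 3 of 4 haemoglobin genes were higher in IT (median log2 ratio 1.61).

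The contrast of IT-TT with TT asks what the antibody added where the combination was given. Lymphocytes of the T and NK class held 14.8% of IT-TT and 1.66% of TT (13.1 points, 11.8 to 14.4) and, among host cells, 28.8% against 10.3% (18.5 points, 14.7 to 21.9). Of immune cells they held 41.4% against 25.3% (16.1 points, 8.69 to 22.6). Macrophages and monocytes held 15.5% against 4.35% (11.1 points, 9.64 to 12.6), with cluster 7 holding most of them in both libraries. Of immune cells, however, they held 43.4% against 66.3% (−22.9 points, −30.1 to −15.2), and of host cells 30.2% against 27.0% (3.23 points, −1.63 to 7.77). In Sox10-positive cells 249 genes passed, 149 higher and 100 lower. Car9, a carbonic anhydrase gene (10.7-fold, 7.77 to 15.1), Edil3 (4.62-fold, 3.87 to 5.54) and Zdhhc2 (3.86-fold, 3.12 to 4.8) were higher, and Gpr179 (9.39-fold, 6.28 to 14.6), Wfdc12 (7.03-fold, 5.63 to 8.87) and the protease inhibitor gene Slpi (6.15-fold, 5.57 to 6.8) lower. MHC class I genes rose in 9 of 21 cases (B2m 2.88-fold, H2-D1 3.6-fold, Psmb8 4.15-fold, H2-T22 2.48-fold). Rises were seen in 6 of 25 interferon gamma response genes (Gbp7 5.51-fold, Igtp 5.99-fold) and for type I interferon genes in 3 of 20 (Bst2 3.26-fold, Ifi27l2a 22.7-fold). MHC class II genes rose in 5 of 9 cases, with H2-Aa at 44.6 against 2.15 CPM and at 4846 CPM in the macrophages and monocytes of IT-TT. MAPK output genes fell in 5 of 21 cases with 0 risen. Egr1 fell 3.04-fold, Phlda1 2.53-fold, Dusp6 2.4-fold (2.21 to 2.6) and Dusp4 2.17-fold. Proliferation genes fell in 1 of 26 cases, Top2a, with a list median of −0.82 at percentile 0.0, and FoxO genes rose in 2 of 18 (Txnip 4.58-fold, Bcl2l11 2.57-fold). Bmp7 fell 3.81-fold (3.07 to 4.79).

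Macrophages and monocytes of IT-TT had 477 genes apart from those of TT, 170 higher and 307 lower. Among them 18 of 26 interferon gamma response genes rose with 0 fallen (Irf1 3.68-fold, Zbp1 3.49-fold). Type I interferon genes rose in 11 of 27 cases (Bst2 2.49-fold, Isg15 2.57-fold), MHC class I genes in 10 of 21 (B2m 2.26-fold, Psmb9 3.3-fold) and MHC class II genes in 8 of 11 (Cd74 2.11-fold, H2-Aa 2.41-fold). Cxcl9 rose 15.7-fold (8.23 to 34.6), Cd274 3.11-fold (1.84 to 5.68) and Ccl5 at least 33.9-fold. Epcam, Cd209d and Ly6i, each at 0 UMIs in TT, were at least 13.8-fold, 12.2-fold and 10.5-fold higher. Epcam was also a top gene of the unnamed epithelial cluster 5, with 97 cells in IT-TT and 2 in TT, and the source of its UMIs in this class was not tested. Proliferation genes fell in 17 of 26 cases with 0 risen, including Birc5 (9.53-fold, 6.76 to 13.6), a mitotic survival gene, and the mitosis genes Cdc20 (13.5-fold, 6.79 to 29.2) and Ccnb1 (14-fold, 6.54 to 33.2) were lower. Mrc1 fell 2.86-fold (2.53 to 3.24), and all 4 haemoglobin genes were lower, with a median log2 ratio of −5.81.

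TMM scaling shifted the log2 ratios of IT-TT against TT by −0.11 in Sox10-positive cells (101 genes higher, 129 lower) and by 0.17 in myeloid cells (256 higher, 191 lower). Thinning left 389 Sox10-positive and 267 myeloid genes and put Cd74, H2-Aa and Cd274 below 2-fold in myeloid cells. Epcam, Cd209d and Ly6i, at 0 UMIs in TT, also went below 2-fold. Their lower bounds must shrink as thinning lowers the class sum, so this does not show a smaller difference. The myeloid share difference was 8.58 points with a mitochondrial limit of 10%. Cluster 3 held 983 of the 1468 Sox10-positive cells of IT-TT and cluster 10 held 1308 of the 2246 of TT.

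The design also gives the change that went with the combination in the presence and in the absence of the antibody. The change in the T and NK share of kept cells was 13.1 points higher with the antibody than without it (11.7 to 14.6). For macrophages and monocytes it was 14.3 points higher (12.4 to 16.4) and for neutrophils 7.69 points higher (6.56 to 9.01). Without the antibody these 2 classes fell, by 2.27 and 2.56 points. As shares of immune cells the same differences were 1.34 points (−8.61 to 11.2) for T and NK cells and −30.1 points (−41.5 to −18.2) for macrophages and monocytes. The T and NK value changed sign with each library clustered alone (−15.0 points) and at a Leiden resolution of 2 (−0.354 points). As shares of host cells they were 6.10 points (−1.15 to 13.8) and 0.021 points (−10.1 to 9.89). In Sox10-positive cells 178 genes were higher and 198 lower in both settings, where 35.9 and 14.7 would be shared if the calls were independent, and 0 genes moved in opposite directions, over 6773 genes measured in both. In macrophages and monocytes 83 genes were higher and 101 lower in both (21.0 and 28.4 if independent), and 69 moved in opposite directions, over 6340 genes chosen in the same way. The melanocyte list had median log2 ratios of 2.87 and 2.13 over the 13 genes measured in both settings, and MAPK output genes −1.32 and −1.17. The difference between the settings on the log2 scale was −1.20 for Dusp6 and −2.18 for Bmp7. Interferon gamma response genes of myeloid cells had medians of 2.17 with the antibody and −1.18 without it, and type I interferon genes 0.63 and −2.36. These differences between settings were not tested.

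**Figure D2:**
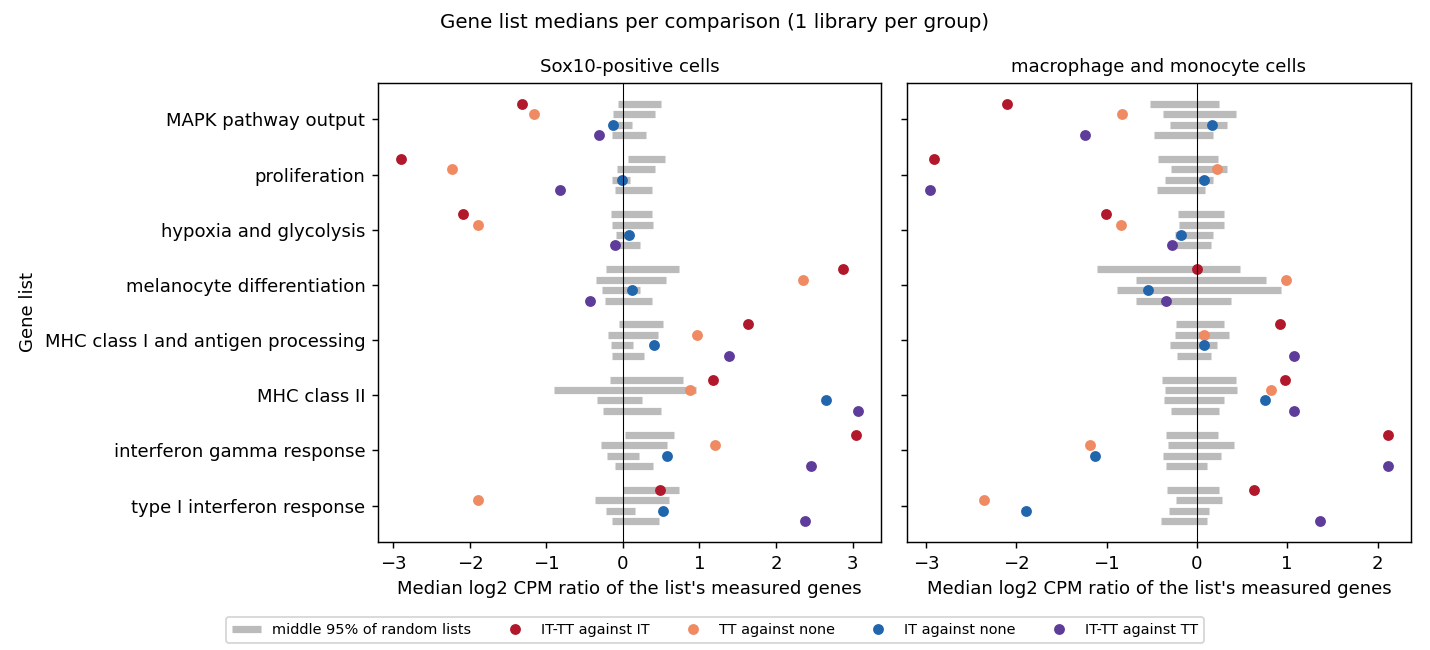
Median log2 CPM ratio of the members of selected fixed gene lists (horizontal axis) for each of the 4 comparisons. Sox10-positive cells are on the left, macrophages and monocytes on the right, and grey bars give the middle 95% of random matched lists. The lists shown are MAPK output, proliferation, hypoxia and glycolysis, melanocyte differentiation, MHC class I, MHC class II, interferon gamma and type I interferon. Interferon gamma response genes of macrophages and monocytes stand at 2.11 for IT-TT against IT and at −1.18 for TT against none.

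Positions of some of the named genes, in mouse build mm10, are as follows. Dct (ENSMUSG00000022129) lies on chromosome 14 from 118012790 to 118052244, Tyrp1 on chromosome 4 from 80834123 to 80851719, Mlana (ENSMUSG00000024806) on chromosome 19 from 29697824 to 29708634, and Cytl1 on chromosome 5 from 37735519 to 37739820. Cd274 lies on chromosome 19 from 29367455 to 29388095, and Bmp7 (ENSMUSG00000008999) on chromosome 2 from 172868012 to 172940321. Pdcd1 lies on chromosome 1 from 94038305 to 94052553, Tox on chromosome 4 from 6686353 to 6991557, Gzmc on chromosome 14 from 56231441 to 56234656, and Chil3 on chromosome 3 from 106147554 to 106167564, and all are annotated as protein-coding genes.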

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

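The tests of the low-UMI cells below were chosen only after the result was seen. Unnamed cells with few UMIs made up 27.5% (27.468%) of the kept cells of IT and at most 3.90% of any other library, with a median of 1014 UMIs per cell. Sox10-positive cells poor in RNA could give such cells, and 11 Sox10-positive markers stood at a median of 0.74 (0.661 to 0.969) of their level in the Sox10-positive cells of IT. This does not decide it, because the cluster was already known to score highest for these markers, and Sox10-positive cells held 34037583 of the 39257406 kept UMIs of IT, so free RNA could give a like value. Droplets holding only free RNA could also give them, and these cannot be told apart here, because 25 abundant host genes stood at 0.574 (0.44 to 0.74) of their level in the whole library, between the 0.5 that would exclude free RNA and the 0.7 it needed.

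Epithelial cells led by keratin genes held 2.98% (2.981%) of IT-TT and were not analysed here. The change in share with the combination was larger with anti-PD1 than without by 14.3 points (14.322) in macrophages and monocytes and by 7.69 points (7.687) in neutrophils, as shares of kept cells, and without anti-PD1 both fell. For macrophages and monocytes it was −30.1 points as a share of immune cells and 0.021 points as a share of host cells. In macrophages and monocytes the median difference of log2 ratios, with minus without anti-PD1, was 3.38 (3.376) for interferon gamma response genes, 3.20 (3.196) for type I interferon response genes, 1.00 (1.002) for T helper 1 genes and 1.04 (1.038) for inflammatory macrophage genes. Haemoglobin genes differed by −7.42 (−7.417) and Cd274 by 3.51 in the same cells. The haemoglobin value rests on a rise without anti-PD1 (2.51) that turned to −3.13 with classes by marker score per cell, where the difference was −2.13, and to a fall of all 4 genes with a mitochondrial limit of 10%. After thinning the log2 ratio behind the Cd274 difference was −0.52 with anti-PD1, on few UMIs. Without anti-PD1 it was set to 0.0, because a count of 0 left no ratio. None of these differences between groups was tested.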

How the results depend on the processing

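Of the values recomputed under other settings, class shares central to the report stayed the same in 78 cases, moved in 9 and turned in 1, and other shares in 277, 68 and 3. Gene counts stayed in 54 cases and moved in 27, log2 ratios of named genes stayed in 2117, moved in 887 and turned in 26, and list medians stayed in 673, moved in 143 and turned in 10. The effect of the combination with against without anti-PD1 stayed in 20 central cases and moved in 2, with 66 and 21 for other shares, and its log2 differences stayed in 139, moved in 10 and turned in 1. Counts of lists stayed in 26 cases and moved in 1, and T cell subsets stayed in 10 and moved in 1. A share stayed if it lay inside the main counting interval, and turned only if that interval excluded 0. Some changes of sign thus count as stayed, such as the regulatory T difference with doublets kept (4.44 to −0.507 points). Gene counts were judged by their total, so TMM scaling of IT-TT against IT in Sox10-positive cells counts as stayed (802 and 683 genes). Its directions shifted, from 535 higher and 267 lower to 224 and 459. The T and NK difference between IT-TT and IT ran from 12.1 to 14.3 points over 11 settings. Unless stated, the cause of a shift was not tested.

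With a mitochondrial limit of 10%, the myeloid share of TT minus none turned to 0.272 points and the Sox10-positive share of IT-TT minus IT to 6.01 (6.011), while the T and NK share of TT minus none moved to 1.52 (1.519), the myeloid share of IT-TT minus TT to 8.58 (8.584) and the myeloid effect with against without anti-PD1 to 11.6 (11.626). Log2 ratios that turned under this limit, added after seeing the data, were Hspa1b (0.124, Sox10-positive, TT against none), Spp1 (−0.052, Sox10-positive, IT-TT against TT), Ccl5 (−0.349, myeloid, IT-TT against IT), H2-DMb2 (−0.411), Hbb-bs (−3.233), Hba-a1 (−4.486), Hba-a2 (−1.063) and Hbb-bt (−2.178) in myeloid cells of TT against none, Hba-a1 (0.017, myeloid, IT-TT against TT) and Ly6a (0.498, T and NK).

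Without a mitochondrial limit, a setting chosen after seeing the data, the Sox10-positive share of IT-TT minus IT turned to 8.53 points (8.525), Spp1 to −0.171 (Sox10-positive, IT-TT against TT) and Ly6a to 0.479 (T and NK), and the T and NK share of IT-TT minus IT moved to 12.1 points (12.107). Without erythroid and unnamed cells, also chosen afterwards, the Sox10-positive share of IT minus none turned to 3.70 points (3.702), and the T and NK and myeloid shares of IT minus none moved to 0.658 and −1.80 (−1.795). With each library clustered alone, the T and NK share moved to 1.66 points for TT minus none and 1.41 (1.412) for IT minus none, and the myeloid share of IT minus none to −4.95 (−4.949). With at least 500 genes per cell the myeloid share of IT-TT minus IT moved to 10.4 points (10.416) and the myeloid effect with against without anti-PD1 to 12.4 (12.378). Gating moved the CD8 share of IT-TT minus IT to −26.5 points (−26.463). Another setting chosen after seeing the data left the reported class markers out of clusters and names. The log2 ratios of those markers that passed the rule of size then stayed inside their counting intervals. They were not all equal to the main values: Chil3 in myeloid cells of IT-TT against IT went from 4.42 to 5.27.

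Without a CPM minimum more genes pass by construction: 2131 (IT-TT against IT), 2134 (TT against none), 367 (IT against none) and 927 (IT-TT against TT) in Sox10-positive cells, and 1624 (IT-TT against IT) and 996 (IT-TT against TT) in myeloid cells. With at least 100 CPM fewer pass by construction, in the same order of comparisons 242, 269, 5 and 69 in Sox10-positive cells, 242, 166, 96 and 98 in myeloid cells, and 195 in T and NK cells. With genes holding RNA from other cells left out, which can only lower the count, Sox10-positive cells kept 10 genes (IT against none) and 146 (IT-TT against TT), and myeloid cells 505, 412, 264 and 265.

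With cells thinned to 1000 UMIs, 59 genes (IT against none) and 389 (IT-TT against TT) passed in Sox10-positive cells, 154 (TT against none), 163 (IT against none) and 267 (IT-TT against TT) in myeloid cells and 239 in T and NK cells, and 8 lists lay outside the middle 95% of random lists in myeloid cells of IT against none. List medians that turned were melanocyte differentiation in Sox10-positive cells of IT-TT against TT (0.062) and, in myeloid cells, alternatively activated macrophage (0.232, IT-TT against IT), chemokines (0.045, TT against none, and −0.348, IT-TT against TT), extracellular matrix (−0.035, IT against none) and FoxO and growth factor withdrawal (−0.037, IT-TT against TT). Genes that turned in myeloid cells were Cd274 (−0.52, IT-TT against IT, and 0.515, IT against none), Tk1 (−1.391), Sox10 (−0.391) and Il1a (0.609) for TT against none, Batf (−0.485) and Postn (−0.07) for IT against none, and Ciita (−0.047) and Fasn (0.926) for IT-TT against TT. In T and NK cells Pik3ip1 (0.231) and Ly6a (0.097) turned.

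With means in place of medians, chemokines (0.192) and extracellular matrix (0.025) turned in Sox10-positive cells of IT-TT against IT, and T helper 1 (−0.195) and lipid-handling macrophage (−0.013) in those of IT against none. With classes by marker score per cell, the myeloid difference for T cell naive or memory genes turned to −0.182. With doublets kept, Spp1 (−0.22, Sox10-positive, IT-TT against TT), Col3a1 (0.975, myeloid, IT-TT against IT) and Apoe (0.577, T and NK) turned.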

Other observations

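Tests of the T and NK share below were chosen only after the result was seen, and that of Dct and Mbp was written before. Fibroblasts, the matrix-building cells of the stroma, made up 54.7% of the host cells of TT and 3.85% of those of none, and 24.3% of those of IT-TT and 10.7% of those of IT. Endothelial cells held 6.01%, 0.578%, 4.58% and 2.20% of host cells in IT-TT, IT, TT and none. Among receptor tyrosine kinase and growth factor receptor genes of Sox10-positive cells, Ngfr, a neural crest receptor gene, rose 18.8-fold (16.4 to 21.5) in IT-TT against IT and 8.52-fold (6.91 to 10.6) in TT against none. Axl, a receptor gene tied to drug tolerance, fell 2.03-fold (1.84 to 2.25) and 4.29-fold (3.87 to 4.77) in the same comparisons. Apoe, a lipid carrier gene, rose 3.52-fold and 7.09-fold, and Spp1, the osteopontin gene, fell 7.2-fold and 20.5-fold.

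Extracellular matrix genes of Sox10-positive cells fell in 5 of 23 cases and rose in 1 in TT against none, with Fn1, the fibronectin gene, 9.29-fold (8.72 to 9.91) and Tnc, the tenascin gene, 4.91-fold lower. In IT-TT against TT they rose in 4 of 22 cases, with Fn1 5.73-fold (5.35 to 6.14) and Tnc 2.35-fold higher. Among BMP and TGF-beta genes in IT-TT against IT, 2 of 20 rose, Id3 (3.11-fold) and Id2 (2.63-fold), and 3 fell, with a median log2 ratio of 0.22 at percentile 31.5. In the macrophage and monocyte class Ccr7 and Ccl17, genes of mature dendritic cells, rose 28.7-fold (7.87 to 239) and 27.4-fold (7.49 to 227) in IT-TT against IT on 2 UMIs each in IT. With a mitochondrial limit of 10% the log2 ratio of Ccr7 was set to 0.0, because a count of 0 left no ratio.

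Dct, a pigment gene, and Mbp, the myelin basic protein gene, stood higher in the Sox10-positive cells of both combination libraries, Dct at 511 (IT-TT), 4.94 (IT), 870 (TT) and 3.88 (none) CPM. Host Schwann cells or melanocytes could bring these genes. A set of 24 genes that host classes express, at most at 6.77 CPM (Btg2) in vehicle Sox10-positive cells, stood at 0.0072 (IT-TT) and 0.0024 (TT) of the host level. This was under the 0.1 set beforehand to exclude such cells. However, the host level came from T and NK cells, macrophages and monocytes, fibroblasts and endothelial cells. Genes shared by those classes stayed near absent, but the levels of these genes in Schwann cells and melanocytes were not measured. The test therefore cannot exclude them. Both genes were markers of the class, and with the reported markers left out of clusters and names their log2 ratios were 6.66 and 2.07 (IT-TT against IT) and 7.81 and 3.52 (TT against none).

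The larger T and NK share of IT-TT than of IT could come from the mitochondrial limit, but without it the difference was 12.1 points (12.107, 11.02 to 13.3), which excluded this. More host tissue in the suspension of IT-TT could also raise it, and among host cells the difference from IT was 4.86 points (4.858, −0.364 to 9.61), an interval that holds 0 and leaves this open. The host total leaves out erythroid cells, 20 in IT-TT and 391 in IT, so this holds for that total only. Against TT the difference among host cells was 18.5 points (18.549, 14.7 to 21.9), while fibroblasts were fewer, 24.3% against 54.7%, which excluded more host tissue of the same make-up but left host tissue of another make-up open. More libraries per group would be needed to separate treatment from tumour-to-tumour variation.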
